A study of Homo sapiens with 16 samples.

How the data were processed

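RNA was measured in 16 libraries of U2OS cells, a human line from a bone tumour that the labels call a sarcoma cell line. The groups came from the labels: empty vector, a short hairpin RNA against PIP4K2A, one against PIP4K2B, or both, each untreated or 6 h after UV-C at 30 J/m2, with 2 libraries in each of 8 groups. Per the labels, the RNA was depleted of ribosomal RNA and made into directional libraries.

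The deposited tables hold 1 library each with 60666 genes, and per the file headers their values are expected counts, which RSEM estimates per gene and which are not normalized. The submitters' processing notes name STAR, SAMtools, RSEM and the GRCh38 genome; their roles, the annotation release and the strand setting are not given in the sources used here. Antisense or overlapping transcripts may therefore have been counted with a gene. The deposited tables also give a length in bases (other than a count), the mean transcript length of a gene weighted by the abundance of its isoforms in that library. Of the gene identifiers 60437 had a symbol, and 58420 were found in GENCODE release 29, which gave positions and gene types on GRCh38. Totals ran from 1.28 to 39.9 M expected counts per library.

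Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10, libraries were scaled with TMM, and a quasi-likelihood model with 1 term per group was fitted to all libraries. Contrasts gave UV against untreated in each of 4 genotypes, each knockdown against empty vector untreated and after UV, the difference of UV responses between each knockdown and empty vector, and the double against each single knockdown. Benjamini-Hochberg adjusted p under 0.05 was called a change. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values were divided by the library total without TMM factors.

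The 25 gene lists, the comparisons, the tests and the alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, and with fry. Members of a list were also adjusted over the list alone. The genes named were PIP4K2A, PIP4K2B and PIP4K2C; the 10 largest rises and 10 largest falls for UV in empty-vector cells and for each untreated knockdown, and 5 and 5 elsewhere, among genes past the test with a mean of at least 5 CPM and, except for differences of responses, no overlap between groups; and up to 4 members of each list past the test, or the 2 with the highest mean CPM where none passed. Clone names and pseudogenes were not named, and the text gives a part of the genes so chosen.

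The library labelled empty-vector untreated replicate 1 differed from all others, so every comparison was repeated without it, and the naming rule was applied to that fit too. This choice was made after seeing the data. The untreated empty-vector group then has 1 library, which is assumed to vary like the other groups.

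Weighted lengths were tested in limma on log2 values for genes with a mean of at least 100 counts, with values from libraries under 10 counts set aside. The long-gene index, the median log2 CPM of genes spanning over 100 kb less that of genes under 10 kb, was compared by an exact two-sided permutation of the libraries. Correlations of fold changes between backgrounds and counts of shared calls were computed across genes. Shared calls were also counted in 10 simulated draws in which no knockdown changed.

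The alternatives were RLE size factors in edgeR, scaling to cytosolic ribosomal protein genes, no filter on low counts, a filter of CPM above 1 in 2 libraries, DESeq2 1.42.0, only the groups compared, the replicate number as a block, and leaving out each library in turn. For lengths, a mean count of 30 or 500 was tried, and for the index, protein-coding genes only, a CPM above 1, spans of 50 and 20 kb and permutation within blocks. Replicate numbers did not pair the groups in a uniform way: over 21 pairs of 7 groups the deviations of replicates correlated from -0.379 to 0.672 with a median of 0. Of these pairs 5 lay over 0.1 and 6 under -0.1, so a factor shared by some of the groups is not excluded. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

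The test was tried on simulated counts with 200 changed genes of 21218 over 16 libraries and 21550 over 15. For the untreated double knockdown against empty vector, changes of 1.5, 2 and 4 fold were recovered in 0, 1.5 and 36.4% of genes over 16 libraries and in 16.4, 77.6 and 100% over 15, the latter with 10 false calls. Smaller changes in untreated cells were therefore mostly not detectable. Splicing at the level of single isoforms or exons was not analysed here.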

Results

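Total RNA depleted of ribosomal RNA was sequenced from U2OS, a human sarcoma cell line, to ask how the PIP4K lipid kinases affect gene expression and splicing. PIP4K2A, PIP4K2B and PIP4K2C encode type II phosphatidylinositol phosphate kinases. The cells carried an empty puromycin vector, a stable short hairpin RNA against PIP4K2A or against PIP4K2B, or hairpins against both. Each of the 4 genotypes was left untreated or collected 6 h after ultraviolet C light (UV) of 30 J/m2, with 2 libraries in each of the 8 groups and 16 libraries in all. Replicates 1 and 2 of the untreated cells held 1.28 and 28.6 M expected counts for empty vector. They held 31.9 and 28 M for the PIP4K2A knockdown, 33.0 and 28.4 for the PIP4K2B knockdown, and 30.3 and 29 for the double knockdown. After UV the totals were 39.9 and 31.7, 33.6 and 36.3, 36 and 31.9, and 32.3 and 32.1 M in the same order. Levels are CPM, counts scaled to the total of each library, as mean ± SD, whereas fold changes also carry a composition factor per library.

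The targeted genes were read first in every library. PIP4K2A (ENSG00000150867; GRCh38 chromosome 10, 22534849 to 22714555, minus strand) stood at 62.9 CPM in empty-vector untreated replicate 2 and at 51.5 and 55.8 CPM in the empty-vector UV libraries. In the PIP4K2A knockdown it was 18.2 and 15.5 CPM untreated and 7.48 and 7.63 CPM after UV, and in the double knockdown 22.9 and 22.9 CPM untreated and 9.11 and 9.07 CPM after UV. PIP4K2B (ENSG00000276293; chromosome 17, 38765689 to 38800126, minus strand) was 107 CPM in empty-vector untreated replicate 2 and 81.7 and 76.1 CPM in the empty-vector UV libraries. It was 26.6 and 23.7 CPM untreated and 14.5 and 15 CPM after UV in the PIP4K2B knockdown, and 17.3 and 19.3 CPM untreated and 11.4 and 12.5 CPM after UV in the double knockdown. The hairpin against PIP4K2A left PIP4K2B at 65.1 to 98.3 CPM, and the hairpin against PIP4K2B left PIP4K2A at 43.2 to 60.6 CPM. The library labelled empty-vector untreated replicate 1 stood apart, with PIP4K2A at 15.6 CPM, inside the range of the PIP4K2A knockdown, beside PIP4K2B at 91.5 CPM. PIP4K2C, which no hairpin targeted, was low there too, at 18.8 CPM against 56.5 to 113 CPM in the other 15, so the low PIP4K2A is no sign of a hairpin by itself.

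**Figure D1:**
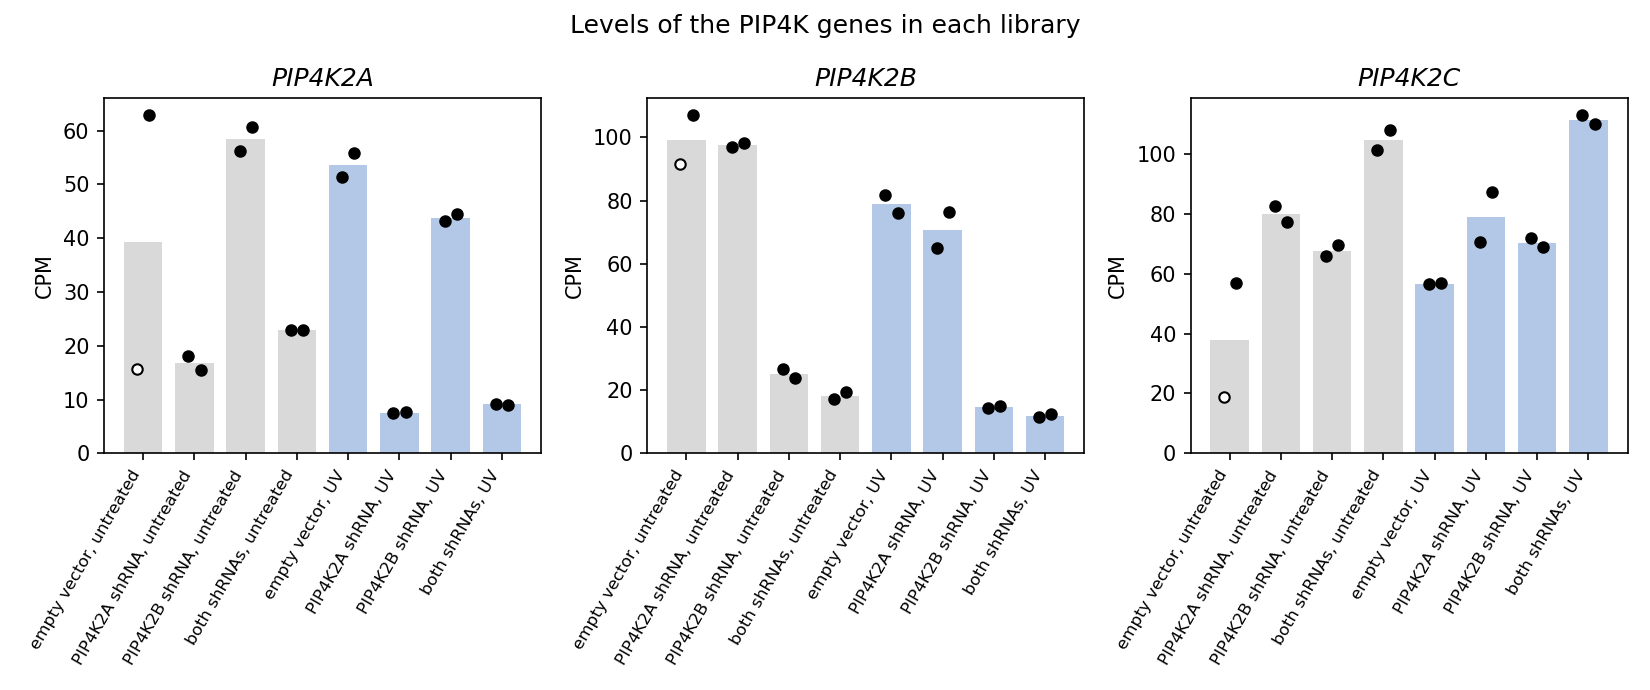
CPM of PIP4K2A, PIP4K2B and PIP4K2C (vertical axes) in each of the 16 libraries, by group (horizontal axis); points are libraries, bars are group means, and the open point is the library labelled empty-vector untreated replicate 1. PIP4K2A lay between 7.48 and 22.9 CPM in the libraries with its hairpin, against 51.5 to 62.9 CPM in the other empty-vector libraries.

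That library stood apart in other ways as well. It held 1.28 M counts where the other 15 held 28 to 39.9 M, and mitochondrial genes took 14.6% of its counts (95% Wilson interval 14.5 to 14.6%, counting error only) against 2.20 to 3.43%. GAPDH, a glycolytic enzyme gene used as a loading control, stood at 771 CPM against 4790 to 8545 CPM. RN7SK, an abundant small nuclear RNA, took 0.236% of counts (0.228 to 0.244%) against 2.81 to 5.88%. Across genes, its log2 CPM correlated with the other libraries at r = 0.408 to 0.512, whereas all pairs of the other 15 lay between 0.944 and 0.998; genes are not independent replicates. The fit planned for all 16 libraries had a biological coefficient of variation of 41.9% over 22090 genes, and the fit without that library 11.4% over 22597 genes. Counts of changed genes are therefore given for both, and fold changes come from the 15-library fit, which was added after the data were seen. In it the untreated empty-vector group is the 1 remaining library, assumed to vary like the libraries of the other groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

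For UV in empty-vector cells, PTGS2, which encodes an inducible cyclooxygenase, rose by 3.80 log2 (SE 0.259), to 35.2 ± 1.13 CPM (n = 2) from 3.01 CPM in the untreated library, although the 16-library fit, which holds the library labelled empty-vector untreated replicate 1, put it at -0.83. The cytokine genes IL11 and GDF15 rose by 3.67 (SE 0.289) and 3.52 (SE 0.288), the immediate early gene ARC by 3.53 (SE 0.25), and the AP-1 genes FOSB and FOS by 2.74 (SE 0.298) and 2.53 (SE 0.186). All 10 of the largest falls under the naming rule were histone genes, among them H2BC11 at -3.62 (SE 0.135), which went from 249 CPM to 16.9 ± 1.6 CPM, and H2AC12 at -3.17 (SE 0.255). Adjusted p ran from 4.21e-08 for H2BC11 to 7.75e-05 for FOSB among these genes (edgeR's quasi-likelihood test, Benjamini-Hochberg). Histone genes are near-identical copies of one another, so the level of any single one is uncertain. PIP4K2A, PIP4K2B and PIP4K2C changed by 0.03, -0.18 and 0.25 log2 and did not pass.

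Of the 25 gene lists fixed before the data were examined, 9 passed limma's camera test for UV in empty-vector cells in the 15-library fit and 15 in the 16-library fit. Among replication-dependent histone genes 0 rose and 15 of 19 fell (18 adjusted over the list alone), with a median of -2.18. Cytosolic ribosomal protein genes had 47 of 78 higher and 0 lower (61 adjusted over the list alone; median 0.70, or -0.01 with ribosomal protein gene scaling, which centres these genes by design; RPL30 1.10), and nuclear-encoded oxidative phosphorylation genes 23 of 48 higher and 0 lower (25 adjusted over the list alone; median 0.51, or -0.20 with that scaling; NDUFA4 1.00). Core spliceosome protein genes had 9 of 38 higher (11 adjusted over the list alone; SF3B6 0.82) and hnRNP genes 3 of 30 higher (3 adjusted over the list alone; HNRNPAB 0.72), neither list had a fall, and their medians of 0.26 and 0.22 became -0.45 and -0.48 with ribosomal protein gene scaling. Lysosome and autophagy genes went both ways, 8 up and 5 down of 39 (9 and 5 adjusted over the list alone), with the autophagosome gene MAP1LC3B at 0.89 and TFEB, a master transcription factor of lysosome genes, at -1.31, and their median of 0.23 became -0.47 with that scaling. Hypoxia and glycolysis genes had 9 up and 5 down of 34 (11 and 6 adjusted over the list alone). Immediate early and AP-1 genes had 13 up and 3 down of 30 (13 and 4 adjusted over the list alone), with the zinc finger factor KLF6 at -1.95. The medians of these last lists, 0.18 and 0.41, became -0.52 and -0.30 with that scaling. FOXO target and insulin signalling genes had 1 up and 6 down of 19 (1 and 8 adjusted over the list alone; median -0.39), among them the pro-apoptotic gene BCL2L11 at -1.65. Camera's Benjamini-Hochberg adjusted p ran from 2.89e-27 for ribosomal protein genes to 0.0227 for hypoxia genes with the preset correlation. With an estimated correlation none of the 9 held: adjusted p = 0.0587 for histone, oxidative phosphorylation, lysosome and FOXO genes, 0.0626 for ribosomal protein genes, and from 0.259 to 0.533 for the other 4 lists.

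The other 16 lists did not pass camera for UV in empty-vector cells, with Benjamini-Hochberg adjusted p from 0.0638 to 0.929. Single members still changed. Of the p53 target genes, 8 rose and 6 fell of 35 (9 and 7 adjusted over the list alone), led by GDF15 and by PMAIP1, a pro-apoptotic gene, at 1.88. NF-kB and inflammatory cytokine genes had 4 up and 1 down of 22 (the same counts adjusted over the list alone), with the chemokine gene CXCL8 at 3.66, or -1.39 over 16 libraries. SR protein and other splicing regulator genes had 2 up and 10 down of 35 (4 and 12 adjusted over the list alone), with RBM5 at -1.46 and the kinase gene CLK2 at -1.12. Cholesterol synthesis and SREBP target genes had 4 up and 6 down of 30 (6 and 6 adjusted over the list alone). Phosphoinositide kinase and phosphatase genes had 2 up and 7 down of 50 (2 and 7 adjusted over the list alone), with the regulatory subunit gene PIK3R1 at -1.56. ATF4 and unfolded protein response genes had 6 up and 5 down of 25, heat shock protein genes 2 and 4 of 15, G1/S genes 4 and 6 of 35, G2/M genes 3 and 6 of 32, and nucleotide excision repair genes 3 and 2 of 31. Extracellular matrix genes had 6 up and 2 down of 34, mitochondrially encoded mRNA genes 2 and 2 of 13, osteoblast lineage genes 1 and 2 of 8, and interferon-stimulated genes 1 and 1 of 23. Adjusted over the list alone these were 6 and 5, 4 and 5, 4 and 6, 3 and 6, 3 and 2, 7 and 2, 2 and 2, 1 and 2, and 1 and 1. Of the markers of other cell types, 0 of 11 epithelial and 0 of 8 blood cell genes passed, over all genes or adjusted over the list alone.

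Over all genes, 209 rose and 2433 fell for UV in empty-vector cells in the 16-library fit, which rests on the library labelled empty-vector untreated replicate 1, and 1959 rose and 2219 fell in the 15-library fit (edgeR). Leaving out empty-vector UV replicate 1 or 2 as well left 2522 or 2379 genes. The direction of moderate UV changes depends on the scaling. Scaled to ribosomal protein genes, all tested genes had a median of -0.68, the split became 154 up and 10249 down, and the median rise of 0.51 for oxidative phosphorylation genes became -0.20, above the all-gene median. The histone median was -2.89 with that scaling.

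The same question was asked of UV in the 3 knockdowns. PTGS2 rose by 3.37 (SE 0.188), 3.47 (SE 0.204) and 3.39 (SE 0.188) log2 in the PIP4K2A, PIP4K2B and double knockdown cells, and ARC by 3.0 (SE 0.183), 3.12 (SE 0.183) and 2.98 (SE 0.184), each with n = 2 per group. FOS rose by 2.91 (SE 0.146) and 3.15 (SE 0.153) in the PIP4K2A and double knockdowns, and GDF15 by 3.10 (SE 0.176) and 3.38 (SE 0.2) in the PIP4K2B and double knockdowns. The membrane protein gene SHISA2 rose by 3.24 (SE 0.122) in the PIP4K2B knockdown, from 3.32 ± 0.321 to 25.5 ± 0.296 CPM. In the double knockdown BMF, a pro-apoptotic gene, fell by 3.25 (SE 0.155) and GAS1, a growth arrest gene, fell by 3.06 (SE 0.191). Over these genes adjusted p ran from 4.58e-08 to 6.31e-07 (edgeR's quasi-likelihood test, Benjamini-Hochberg). PIP4K2A went lower after UV in the cells carrying its hairpin, at -0.90 (SE 0.099) in the PIP4K2A knockdown and -1.01 (SE 0.098) in the double knockdown, and PIP4K2B in the PIP4K2B knockdown at -0.47 (SE 0.105). PIP4K2C rose by 0.36 (SE 0.096) and 0.42 (SE 0.096) in the PIP4K2B and double knockdowns, and both turned to -0.55 and -0.49 with ribosomal protein gene scaling.

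Histone genes fell in each knockdown after UV, 18, 18 and 17 of 19 with medians of -1.66, -1.54 and -1.80 (the same counts adjusted over the list alone; adjusted p = 0.0677, 0.078 and 0.0828 with an estimated correlation, camera, Benjamini-Hochberg). Oxidative phosphorylation genes rose, 34, 41 and 38 of 48 (39, 43 and 42 adjusted over the list alone), and their calls held with an estimated correlation at adjusted p = 0.0473, 0.0243 and 0.0332 (camera, Benjamini-Hochberg). Their member NDUFS6 stood at 1.96 in the PIP4K2A knockdown, but its 2 UV libraries differed widely (an SD of 11 CPM, against 3.68 ± 0.149 CPM untreated). So did those of the members with the next largest changes there, NDUFS5 (32.8 ± 25.1 CPM after UV), NDUFA13 (20.8 ± 15.8 CPM) and NDUFB8 (27.2 ± 15.9 CPM). Lysosome and autophagy genes rose in 20, 24 and 25 members of 39 and fell in 5 each time (23 and 6, 25 and 5, and 27 and 5 adjusted over the list alone). Their adjusted p was 0.0473, 0.0243 and 0.0281 with an estimated correlation (camera, Benjamini-Hochberg). With ribosomal protein gene scaling the medians of both lists turned negative, from -0.07 to -0.20 for oxidative phosphorylation and from -0.37 to -0.51 for lysosome genes, above all-gene medians of -0.67, -0.91 and -0.89. FOXO target genes fell in the double knockdown, 11 of 19 with 3 higher (the same adjusted over the list alone), including BCL2L11 at -1.84, with adjusted p = 0.0448 with an estimated correlation (camera, Benjamini-Hochberg). Over 16 libraries these list medians kept their sign, but with an estimated correlation camera called 0 lists in each knockdown (1 each at an unadjusted p under 0.05), and fry called 0. The 16-library fit called 21 genes up and 97 down in the PIP4K2A knockdown, 30 and 143 in the PIP4K2B knockdown and 36 and 231 in the double knockdown (edgeR), although none of these contrasts uses the divergent library itself. The 15-library fit called 3755 and 3166, 3951 and 3490, and 4312 and 3645, which became 236 and 12201, 132 and 15133, and 125 and 15157 with ribosomal protein gene scaling. Without PIP4K2B knockdown replicate 1, the untreated or the UV library, 4850 or 4453 genes were called in that line, and without double knockdown untreated replicate 1, UV replicate 1 or UV replicate 2, 4956, 5030 or 5025 were in that line.

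Markers of other cell types moved with UV in the knockdowns too. Of the epithelial markers 5 of 11 rose in each, and 1, 0 and 0 fell (5 and 1, 6 and 0, and 5 and 0 adjusted over the list alone), with the keratin gene KRT8 at 0.90, 0.93 and 0.79 (-0.12 in the double knockdown with ribosomal protein gene scaling) and KRT18 at 1.18 in the PIP4K2A knockdown. The list passed camera in the PIP4K2B knockdown, at adjusted p = 0.0292 with the preset and 0.313 with an estimated correlation (Benjamini-Hochberg), and its medians of 0.39, 0.85 and 0.73 became -0.30, -0.07 and -0.18 with ribosomal protein gene scaling. Of 8 blood cell markers 0, 1 and 0 rose and 1, 1 and 0 fell, among them CD4 at -1.87 and -1.31 in the single knockdowns, from 0.948 ± 0.276 and 0.831 ± 0.317 CPM (0 and 1, 0 and 0, and 0 and 0 adjusted over the list alone).

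**Figure D2:**
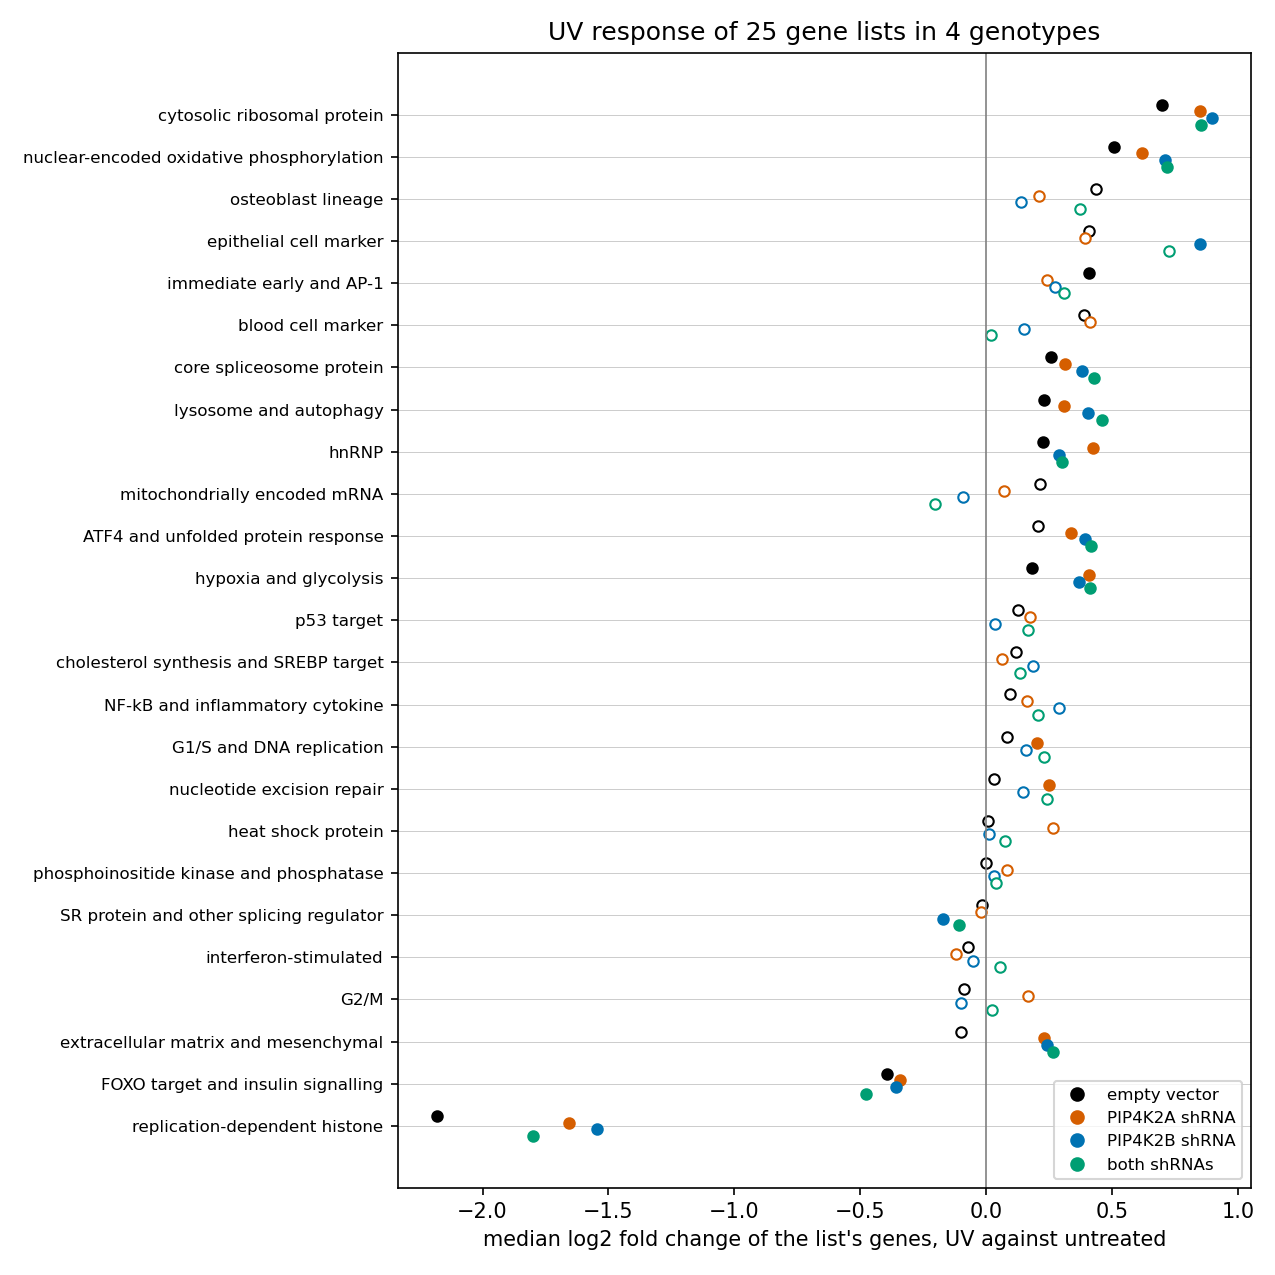
Median log2 fold change of each of the 25 gene lists (rows) for UV against untreated in the 4 genotypes (colours), in the 15-library fit; filled points passed camera with the preset correlation (Benjamini-Hochberg adjusted p under 0.05), and open points did not. Histone genes lay at -2.18, -1.66, -1.54 and -1.80 in empty-vector, PIP4K2A, PIP4K2B and double knockdown cells and ribosomal protein genes at 0.70, 0.85, 0.90 and 0.85; with ribosomal protein gene scaling all 25 medians lay at or below 0 except 0.17 for ribosomal protein genes in the PIP4K2A knockdown.

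Untreated PIP4K2A knockdown cells were compared with empty vector. In this and the other comparisons with empty vector, no hairpin without a target was used. Loss of the kinase, effects of a hairpin as such and differences between the stable lines therefore cannot be told apart. PIP4K2A fell by 1.94 log2 (SE 0.108), to 16.9 ± 1.86 CPM (n = 2) from 62.9 CPM, while PIP4K2B changed by -0.17 and did not pass. ANXA10, an annexin gene, rose by 5.39 (SE 0.46), from 0.454 to 19.7 ± 2.3 CPM, the complement gene C3 by 3.43 (SE 0.371), the laminin chain gene LAMA3 by 3.27 (SE 0.236) and the tight junction gene CLDN1 by 2.62 (SE 0.16). The receptor gene NOTCH3 fell by 2.24 (SE 0.139), from 174 to 37.8 ± 4.43 CPM, and IGFBP4, an insulin-like growth factor binding protein gene, fell by 2.78 (SE 0.201). PIP4K2C rose by 0.46 (SE 0.121). Adjusted p ran from 2.97e-06 for PIP4K2A to 0.038 for PIP4K2C (edgeR's quasi-likelihood test, Benjamini-Hochberg). Of the p53 target genes 15 of 35 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.42), with GDF15 at 1.65 and MDM2, the ubiquitin ligase gene for p53, at 0.91. ATF4 and unfolded protein response genes fell in 9 of 25 members (13 adjusted over the list alone; DDIT4 -1.77, ASNS -0.82, or 0.08 over 16 libraries), cholesterol synthesis genes in 7 of 30 (1 up and 14 down adjusted over the list alone; LSS -0.99, SCD -0.84), and hypoxia and glycolysis genes in 11 of 34 with 2 higher (16 and 3 adjusted over the list alone; ALDOC -1.43).

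These 4 lists held with an estimated correlation, at adjusted p = 0.00454, 0.0225, 0.0225 and 0.0255 (camera, Benjamini-Hochberg), and kept their sign with ribosomal protein gene scaling. Over 16 libraries, however, the medians of the ATF4, cholesterol and hypoxia lists were 0.24, 0.34 and 0.15, so their falls rest on leaving out the divergent library. Camera called 15 lists upward and 1 downward there, and 0 with an estimated correlation (0 at an unadjusted p under 0.05, and 0 by fry). NF-kB genes had 7 of 22 higher (7 up and 1 down adjusted over the list alone; TRAF1 1.91) at adjusted p = 0.193 with an estimated correlation (camera, Benjamini-Hochberg). Of 11 epithelial markers 2 rose and 1 fell (3 and 1 adjusted over the list alone), KRT8 at 1.28, EPCAM at 0.93 and the tight junction gene CLDN4 at -0.81, and that list did not pass camera. The 16-library fit called 24 genes up and 15 down in untreated PIP4K2A knockdown cells and the 15-library fit 838 up and 933 down (edgeR); the second split became 1082 up and 249 down with ribosomal protein gene scaling, which moved the median of all genes by 0.25. Without PIP4K2A knockdown untreated replicate 1 the 15-library count was 780. Only 1 empty-vector library underlies the untreated directions in that fit, and the 16-library directions rest on the library labelled empty-vector untreated replicate 1 as well. Across autosomal genes of at least 5 CPM, fold changes against empty vector also followed the GC content of transcripts. Spearman rho was -0.437, -0.344 and -0.294 in the untreated PIP4K2A, PIP4K2B and double knockdowns, and -0.237, 0.221 and 0.122 after UV. Calls and lists were not adjusted for this trend, so a technical part was not removed.

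In untreated PIP4K2B knockdown cells PIP4K2B fell by 2.06 log2 (SE 0.118), to 25.1 ± 2.01 CPM (n = 2) from 107 CPM, while PIP4K2A changed by -0.08 and PIP4K2C by 0.28, and neither passed. ANXA10 rose by 6.42 (SE 0.458), to 38.4 ± 1.02 CPM, CLDN1 by 2.95 (SE 0.161), GDF15 by 2.61 (SE 0.291) and the axon guidance gene SEMA3A by 2.40 (SE 0.184). The serotonin receptor gene HTR2A fell by 3.28 (SE 0.172), the glycosyltransferase gene GALNT15 fell by 3.17 (SE 0.231) and the long noncoding RNA MIAT fell by 2.55 (SE 0.142). Adjusted p ran from 1.12e-06 for CLDN1, HTR2A and MIAT to 0.000142 for GDF15 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Of the p53 target genes 20 of 35 rose and 0 fell (26 adjusted over the list alone; median 0.60), with GADD45A at 1.16 and ZMAT3 at 1.14. Cholesterol synthesis genes fell in 15 of 30 (17 down and 1 up adjusted over the list alone; median -0.38; INSIG1 -1.12, SCD -1.01), ATF4 genes in 7 of 25 (10 adjusted over the list alone; DDIT4 -1.39), and G2/M genes rose in 12 of 32 (15 adjusted over the list alone; HMMR 1.03, CDK1 0.71). These 4 lists held with an estimated correlation, at adjusted p = 0.000811, 0.011, 0.0398 and 0.0398 (camera, Benjamini-Hochberg). Over 16 libraries the cholesterol and ATF4 medians were 0.20 and 0.21, so these falls rest on leaving out the divergent library. Camera called 17 lists upward and 0 downward there, and 0 with an estimated correlation (2 at an unadjusted p under 0.05, and 0 by fry). Of 11 epithelial markers 1 rose and 2 fell (the same counts adjusted over the list alone), KRT8 at 1.13, KRT14 at -2.41 and CLDN4 at -0.79. NF-kB genes had 6 of 22 higher (7 adjusted over the list alone; TRAF1 2.46) at adjusted p = 0.0956 with an estimated correlation (camera, Benjamini-Hochberg). The counts were 73 up and 84 down over 16 libraries and 1188 up and 1128 down over 15 (edgeR), the latter 917 and 452 with ribosomal protein gene scaling, and 1099 or 1463 genes without PIP4K2B knockdown untreated replicate 1 or 2.

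With both hairpins, untreated cells had PIP4K2A lower by -1.48 log2 (SE 0.108), PIP4K2B by -2.58 (SE 0.119) and PIP4K2C higher by 0.85 (SE 0.123), at 105 ± 4.55 CPM (n = 2) against 56.9 CPM. MAGEA10, a cancer-testis antigen gene, rose by 5.29 (SE 0.231), from 0.699 to 28 ± 0.33 CPM, the vesicle fusion gene VAMP8 by 3.55 (SE 0.352), the pregnancy glycoprotein gene PSG4 by 2.79 (SE 0.22) and MOB3B, a kinase activator gene, by 2.65 (SE 0.127). SERPINF1, a secreted serpin gene, fell by 2.68 (SE 0.211), DHRS2, a dehydrogenase gene, fell by 1.89 (SE 0.221) and NOTCH3 fell by 1.80 (SE 0.138). Adjusted p ran from 3.01e-07 for MAGEA10, PIP4K2B and MOB3B to 0.0014 for PIP4K2C (edgeR's quasi-likelihood test, Benjamini-Hochberg). PSG4 belongs to a family of near-identical copies, so its level is uncertain. Of the p53 target genes 7 of 35 rose and 0 fell (16 and 1 adjusted over the list alone; median 0.28), with TP53INP1 at 0.97, and ATF4 genes fell in 8 of 25 (12 down and 1 up adjusted over the list alone), with the asparagine synthetase gene ASNS at -1.29. Both held with an estimated correlation, at adjusted p = 0.0183 and 0.0331 (camera, Benjamini-Hochberg). Over 16 libraries the ATF4 median was 0.047 and camera called 14 lists upward and 1 downward, and 0 with an estimated correlation (0 at an unadjusted p under 0.05, and 0 by fry). Of 11 epithelial markers 2 rose and 0 fell (3 and 1 adjusted over the list alone), KRT8 at 1.35 and CDH1 at 0.86, the latter -0.15 over 16 libraries. Cholesterol synthesis genes had 4 of 30 lower (4 adjusted over the list alone; median -0.14, which turned to 0.02 with ribosomal protein gene scaling) at adjusted p = 0.213 with an estimated correlation (camera, Benjamini-Hochberg). The counts were 30 up and 15 down over 16 libraries and 732 up and 669 down over 15 (edgeR), the latter 647 and 210 with ribosomal protein gene scaling, and 518 or 655 genes without double knockdown untreated replicate 1 or 2.

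After UV the same 3 comparisons use neither untreated empty-vector library. In the PIP4K2A knockdown PIP4K2A fell by 2.87 log2 (SE 0.1), to 7.56 ± 0.108 CPM from 53.6 ± 3.07 CPM (n = 2 each), ANXA10 rose by 5.05 (SE 0.31) and LAMA3 by 4.47 (SE 0.192), and IGFBP4 fell by 3.11 (SE 0.179). In the PIP4K2B knockdown PIP4K2B fell by 2.34 (SE 0.106), ANXA10 rose by 6.08 (SE 0.31), the cadherin gene DCHS2 rose by 2.23 (SE 0.081) and GALNT15 fell by 3.44 (SE 0.223). In the double knockdown PIP4K2A fell by 2.51 (SE 0.098) and PIP4K2B fell by 2.68 (SE 0.109), MAGEA10 rose by 5.42 (SE 0.164) and VAMP8 by 3.58 (SE 0.244), and CSTA, a protease inhibitor gene, fell by 2.60 (SE 0.17). Over these genes adjusted p ran from 3.22e-09 to 2.26e-06 (edgeR's quasi-likelihood test, Benjamini-Hochberg). PIP4K2C rose by 0.44, 0.39 and 1.02. Without the divergent library the fits called 2563 genes up and 2035 down, 2413 and 1875, and 1921 and 1550 (edgeR), against 41 and 19, 74 and 53, and 47 and 17 over 16 libraries. With ribosomal protein gene scaling the 15-library splits were 5025 and 713, 1284 and 1635, and 1038 and 1113. Replicates 1 and 2 of the PIP4K2A knockdown after UV differed more than other pairs, with a chi-square per degree of freedom of 94.4 against 1.80 to 21.1 in the groups other than untreated empty vector, and leaving out replicate 2 gave 6771 genes. Without empty-vector UV replicate 1 or 2 the counts fell to 2595 or 2218, 2176 or 2448, and 1617 or 1838; without replicate 1 or 2 of the knockdown they fell to 2056 or 2357 for PIP4K2B and 1529 or 1465 for the double knockdown.

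The p53 target genes were higher after UV too, 16 up and 2 down, 24 up and 1 down, and 17 up and 1 down of 35 in the PIP4K2A, PIP4K2B and double knockdowns (20 and 2, 30 and 1, and 22 and 2 adjusted over the list alone). Their medians were 0.29, 0.47 and 0.42, with ZMAT3 at 1.15, 1.04 and 0.83, and adjusted p = 0.0146, 0.00114 and 0.00385 with an estimated correlation (camera, Benjamini-Hochberg). Cholesterol synthesis genes fell in the single knockdowns, 14 and 13 of 30 and none higher (15 down and 1 up, and 16 down, adjusted over the list alone), with INSIG1 at -1.16 and -1.10, and adjusted p = 0.0364 and 0.0154 with an estimated correlation (camera, Benjamini-Hochberg). Their medians of -0.30 and -0.34 became -0.03 and -0.42 with ribosomal protein gene scaling. G2/M genes rose in 19 of 32 in the PIP4K2A knockdown (19 adjusted over the list alone; HMMR 0.95, TPX2 0.67) at adjusted p = 0.0397 with an estimated correlation (camera, Benjamini-Hochberg). In the double knockdown lysosome and autophagy genes had 15 up and 1 down of 39 (21 and 1 adjusted over the list alone), with TFEB at 1.15 and the glycoprotein gene GPNMB at 0.99, and adjusted p = 0.00385 with an estimated correlation (camera, Benjamini-Hochberg). Over 16 libraries the medians of the lists named here kept their sign, but with an estimated correlation camera called 0 lists in each knockdown (1, 1 and 0 at an unadjusted p under 0.05) and fry 1, 1 and 0. Of 11 epithelial markers 5, 2 and 3 rose and 1, 3 and 1 fell (the same counts adjusted over the list alone), and that list did not pass camera. KRT8 stood at 1.70, 1.58 and 1.67 and CLDN4 at -1.58, -1.03 and -1.09 in the 3 knockdowns. EPCAM and CDH1 rose in the PIP4K2A knockdown (1.16 and 0.95) and the double knockdown (0.86 and 1.06), whereas KRT14 and KRT5 fell in the PIP4K2B knockdown (-1.87 and -0.73).

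**Figure D3:**
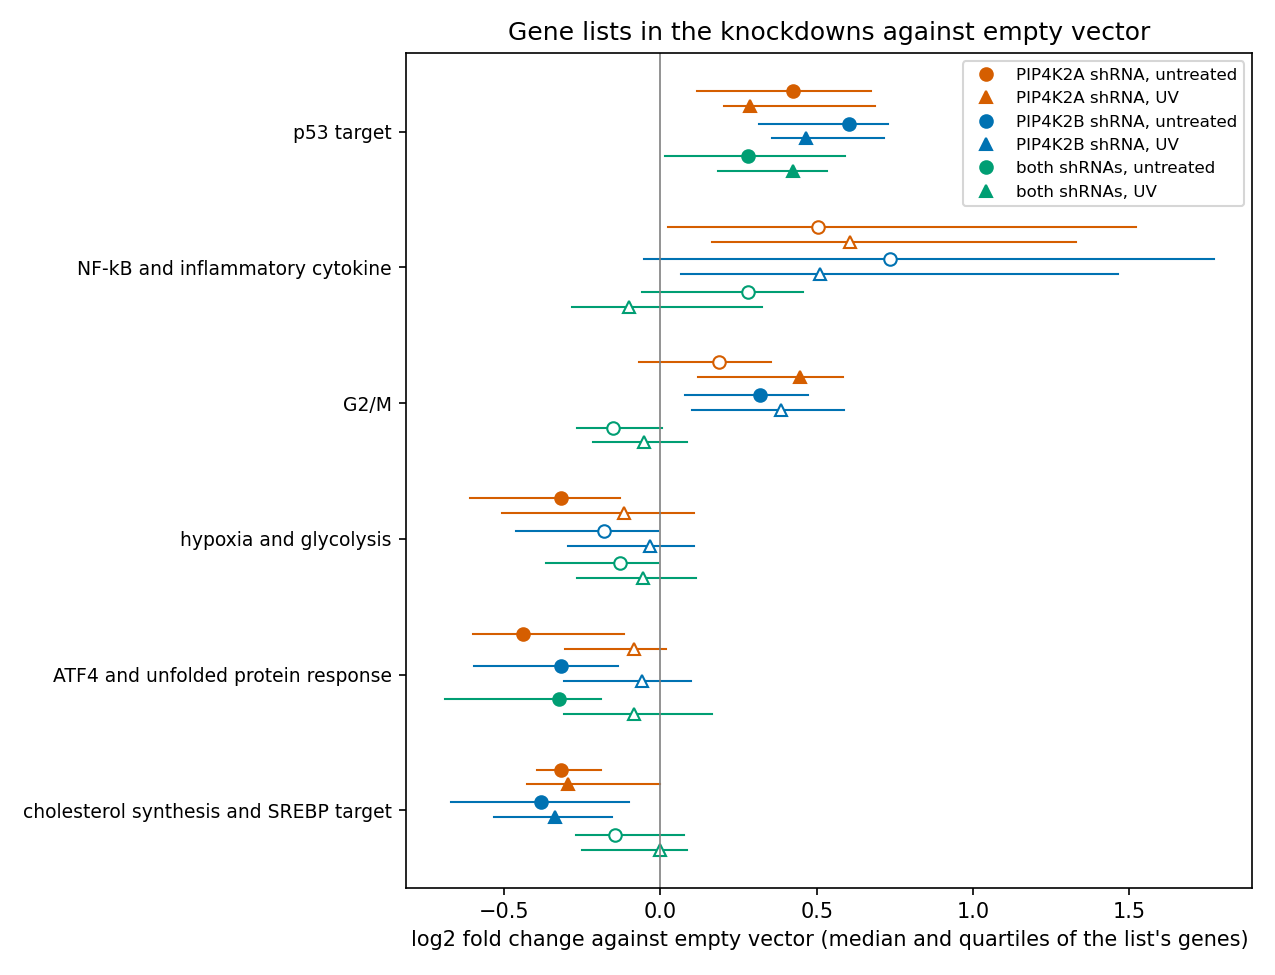
Median log2 fold change of 6 gene lists in the 3 knockdowns against empty vector (colours), untreated (circles) and after UV (triangles), in the 15-library fit; bars span the lower to the upper quartile of each list's genes, and filled symbols passed camera with an estimated correlation (Benjamini-Hochberg adjusted p under 0.05). The p53 target medians lay between 0.28 and 0.60 in all 6 comparisons, and those of cholesterol synthesis genes between -0.38 and 0.00; with ribosomal protein gene scaling the p53 medians stayed above 0 and the medians that turned positive were 0.02 for cholesterol, 0.03 for hypoxia and 0.01 for G2/M genes in the untreated double knockdown and 0.15 for hypoxia and 0.18 for ATF4 genes in the PIP4K2A knockdown after UV.

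The knockdowns shared many of their calls in the same direction. A smaller number of genes was called in opposite directions, most for the PIP4K2B and double knockdowns. Untreated, 609 genes rose and 572 fell in both single knockdowns, 329 and 350 in the PIP4K2A and double knockdowns, and 296 and 296 in the PIP4K2B and double knockdowns, whereas independent lists would share 44.1 and 46.6, 27.2 and 27.6, and 38.5 and 33.4. After UV the shared counts were 1262 and 821, 872 and 653, and 827 and 600, against 274 and 169, 218 and 140, and 205 and 129 for independent lists. Unchanged groups simulated against the same controls shared at most 1 call in 10 draws. With no change an adjusted test calls few genes, so this does not show how many shared calls come from the controls. The covariance of the fold changes was 0.599, 0.517 and 0.473 untreated and 0.417, 0.323 and 0.325 after UV, against simulated values of 0.243, 0.241 and 0.242 and of 0.11, 0.11 and 0.109. The correlations were 0.735, 0.694 and 0.602 untreated against simulated 0.72, 0.723 and 0.723, and 0.557, 0.458 and 0.459 after UV against 0.492, 0.486 and 0.476. Over 15 libraries the correlation lay above its simulated value for the single knockdowns, only slightly so untreated, and below it for pairs with the double knockdown. The spread of the simulated correlations is not known, and the covariances lay above their simulated values in every pair. Changes that are not shared lower a correlation, so a value below the simulated one does not show that shared changes are absent. Over 16 libraries the correlation was 0.935, 0.93 and 0.903 untreated against simulated 0.599, 0.598 and 0.6, above these in all 3 pairs. After UV it was 0.569, 0.47 and 0.459 against 0.495, 0.495 and 0.488, above these for the single knockdowns alone. Part of each excess over independent lists may come from the shared controls, which are too few to split. In the 16-library fit the shared counts were 20 and 13, 11 and 5, and 11 and 8 untreated, and 28 and 7, 22 and 3, and 18 and 6 after UV. Genes of some chromosomes also moved together. The 380 tested genes of chromosome 15 with at least 5 CPM had medians from 0.16 to 0.31 in the 6 comparisons. Chromosome 20 had medians of 0.125, 0.095 and -0.087 in the untreated PIP4K2A, PIP4K2B and double knockdowns, and 0.156, 0.183 and -0.035 after UV. Those of chromosome 10 were -0.119, -0.166 and -0.016 untreated and -0.119, -0.183 and -0.052 after UV.

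Whether a knockdown changed the response to UV was tested as an interaction. In the 16-library fit edgeR called 0 genes for each knockdown, with 2321, 1995 and 1906 genes at an unadjusted p under 0.05, and DESeq2 called 21, 14 and 7. In the 15-library fit DDIT4, an mTORC1 inhibitor and ATF4 target gene, had a UV change higher by 1.47 log2 (SE 0.171) in the PIP4K2A knockdown than in empty vector, at an adjusted p of 0.0151 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The other call there, RIMBP3C at -8.95, lies outside the naming rule, was chosen after its values were seen, and belongs to a family of near-identical copies. In the double knockdown the UV changes of SOX9, a developmental transcription factor gene, and TRIB1, a pseudokinase gene, were lower by -1.22 (SE 0.136) and -1.09 (SE 0.141), at adjusted p of 0.0185 and 0.0469 (edgeR's quasi-likelihood test, Benjamini-Hochberg). For the PIP4K2B knockdown edgeR called 0, with 1655 genes at an unadjusted p under 0.05, and DESeq2 called 18; DESeq2 called 23 and 20 for the others. These counts rested on single libraries: without PIP4K2A knockdown UV replicate 2 the first became 1866, with UV replicate 1 left out 12, with untreated replicate 2 left out 4, with empty-vector UV replicate 1 left out 1, and without PIP4K2A knockdown untreated replicate 1 or empty-vector UV replicate 2 it became 0. The double knockdown count was 1 without its UV replicate 2 and 0 without any other of its libraries or those of empty-vector UV. For PIP4K2A itself the interaction was -0.93 (SE 0.149) and -1.03 (SE 0.148) in the cells with its hairpin and did not pass.

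Of the lists, 10, 10 and 11 passed camera as interactions over 15 libraries, and 2 held with an estimated correlation, both in the double knockdown. There the ATF4 and unfolded protein response genes changed more upward with UV than in empty vector, by a median of 0.25, and so did lysosome and autophagy genes, by 0.17, each at adjusted p = 0.0186 with an estimated correlation (camera, Benjamini-Hochberg). Over 16 libraries both medians reversed, to -0.21 and -0.48, and camera called 1 list upward and 13 downward, and 0 with an estimated correlation (0 at an unadjusted p under 0.05, and 0 by fry). Scaled to ribosomal protein genes over 15 libraries the medians were 0.05 and -0.04, above an all-gene median of -0.20, so that of the lysosome genes turned. Single members were 6 ATF4 genes up when adjusted over the list alone and 0 over all genes, and 0 lysosome genes by either.

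Double knockdown cells were compared with each single knockdown, which share no empty-vector library. Against untreated PIP4K2A knockdown cells PIP4K2B was lower by -2.40 log2 (SE 0.106), and against untreated PIP4K2B knockdown cells PIP4K2A was lower by -1.40 (SE 0.093). MAGEA10 was higher by 5.29 (SE 0.169) and 5.37 (SE 0.171), at 28 ± 0.33 CPM against 0.722 ± 0.0899 and 0.643 ± 0.163 CPM (n = 2 each), and HEPH, a copper-dependent ferroxidase gene, by 2.27 (SE 0.158) and 3.57 (SE 0.178). ANXA10 was lower by -2.35 (SE 0.25) and -3.38 (SE 0.252) and SEMA3A by -2.16 (SE 0.143) and -2.71 (SE 0.143). Against the PIP4K2B knockdown NLRP2, an inflammasome family gene, was higher by 5.19 (SE 0.162), GTSF1, a germline gene, by 4.24 (SE 0.145) and HTR2A by 4.16 (SE 0.155). After UV MAGEA10 was higher by 5.10 (SE 0.159) and 4.81 (SE 0.157), and CDKN2B, a cyclin-dependent kinase inhibitor gene, by 5.52 (SE 0.194) against the PIP4K2B knockdown. Adjusted p ran from 1.53e-09 for MAGEA10 and NLRP2 to 0.000134 for ANXA10 over these genes (edgeR's quasi-likelihood test, Benjamini-Hochberg). PIP4K2C was higher in the double knockdown in all 4 comparisons, by 0.40, 0.58, 0.58 and 0.63.

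Between double and single knockdowns the 15-library fit called 798 genes up and 806 down against PIP4K2A and 1655 and 1822 against PIP4K2B untreated, and 2217 and 2195, and 1953 and 2053 after UV (edgeR). The 16-library counts were 12 and 9, 64 and 38, 16 and 15, and 99 and 51. With ribosomal protein gene scaling the splits against the PIP4K2A knockdown were 327 and 554 untreated and 623 and 5093 after UV, and those against the PIP4K2B knockdown 1307 and 995 untreated. Left out 1 at a time, PIP4K2A knockdown untreated replicate 1 and double knockdown untreated replicates 1 and 2 gave 739, 664 and 583 genes for the first comparison. For the second, PIP4K2B knockdown untreated replicates 1 and 2 gave 1782 and 2154 and the same double knockdown libraries 1847 and 1849. After UV, double knockdown replicates 1 and 2 gave 1923 and 1927 against PIP4K2A and 2141 and 2106 against PIP4K2B, and PIP4K2B knockdown UV replicates 1 and 2 gave 2159 and 2266. Across genes, the fold changes of the PIP4K2B hairpin in 2 backgrounds that share no library, PIP4K2B knockdown against empty vector and double against PIP4K2A knockdown, correlated at r = -0.20 (rho = -0.28) untreated and -0.12 (rho = -0.11) after UV over 22597 genes. Those of the PIP4K2A hairpin correlated at r = -0.12 (rho = -0.16) and -0.12 (rho = -0.13). These values depend on the filter: over the 11569 genes with a mean of at least 5 CPM, r was -0.421 (rho = -0.448) untreated and -0.205 after UV for the PIP4K2B hairpin, and -0.228 and -0.182 for the PIP4K2A hairpin. In the 16-library fit, whose untreated values rest on the library labelled empty-vector untreated replicate 1, r was 0.04 and -0.02 untreated and -0.13 and -0.13 after UV. Genes are not independent replicates, so no p is given.

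Splicing was approached through the abundance-weighted transcript length of each gene, since the tables used here give genes and not isoforms. After UV in empty-vector cells the carnitine palmitoyltransferase gene CPT1B had a length of 1809 bases against 928 (0.96 log2, SE 0.097) and MARF1, an RNA-binding protein gene, 6636 against 3962 (0.74, SE 0.086). COG3, a Golgi transport gene, went from 2984 to 959 bases (-1.64, SE 0.228), SSH2, a phosphatase gene, from 2586 to 1264 (-1.03, SE 0.104), and FBXW7, a ubiquitin ligase subunit gene, from 3061 to 1679 (-0.87, SE 0.075), with adjusted p from 0.00857 to 0.028 over these genes (limma, Benjamini-Hochberg). Lengths shifted for 3 genes up and 6 down over 16 libraries and 41 up and 33 down over 15, of 11493 and 11545 genes, and for 11 or 12 genes without empty-vector UV replicate 1 or 2. In the untreated knockdowns ADAMTS6, a metalloprotease gene, had a longer weighted length in the PIP4K2A and PIP4K2B knockdowns (0.66, SE 0.066, and 0.63, SE 0.066), the zinc finger gene ZNF746 in all 3 (0.23, 0.23 and 0.24) and the noncoding RNA LINC00662 in the PIP4K2A and double knockdowns (0.20 and 0.30). ANXA10, which also rose in level, had a shorter one in the single knockdowns (-0.30 in both). Its level in the only untreated empty-vector library was low, so its length there rests on few counts. The changes of these genes passed in limma (Benjamini-Hochberg). These calls numbered 4, 4 and 3 over 15 libraries and 0 over 16 in limma, where 1200, 1263 and 1130 genes had an unadjusted p under 0.05, and the calls in each single knockdown became 0 without replicate 1 or without replicate 2 of that knockdown. After UV the counts were 2, 0 and 0 over 15 libraries and 0 over 16, with 408, 207 and 168 genes at an unadjusted p under 0.05 over 16. Without PIP4K2A knockdown UV replicate 2 the first became 1720, without replicate 1 it became 7, and without empty-vector UV replicate 2 it became 0. In simulated data for the double knockdown after UV, limma recovered 12, 24, 64 and 94% of changes of 0.1, 0.25, 0.5 and 1 log2, so small shifts were mostly not detectable. The simulation also gave 5 false calls beside the planted changes it recovered. An adjusted test allows more false calls where more true changes are called. These 5 therefore do not tell how many of the knockdown calls are false.

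UV lesions block elongating polymerase, so long genes were compared with short ones. The median log2 CPM of 3591 genes spanning over 100 kb, less that of 7267 genes under 10 kb, was higher after UV by 0.20 in 8 against 8 libraries (exact two-sided permutation test, p = 0.329, 12870 splits), which rests on the library labelled empty-vector untreated replicate 1. Without it the difference was 0.02 (exact permutation p = 0.659, 6435 splits). Among protein-coding genes only, 3189 long against 3031 short, long genes were lower after UV by -0.36 (exact permutation p = 0.00171). Without that library they were lower by -0.27 (exact permutation p = 0.00311). These permutations moved single libraries across genotypes and took libraries of the same group as independent, which the labels do not show. Permutation within blocks was run for the index of all genes only. The 15-library protein-coding difference was -0.15 in empty-vector, -0.16 in PIP4K2A knockdown, -0.37 in PIP4K2B knockdown and -0.35 in double knockdown cells, lower in 4 of 4 genotypes.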

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

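The tests in this part come from the 15-library fit, which was chosen after the data were seen. Each value is the UV change in a knockdown less the UV change in empty-vector cells, on the log2 scale, and is given here because a test of that difference itself passed. All of them rest on the 1 remaining untreated empty-vector library.

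Single genes that passed under the naming rule were DDIT4 (1.47) in the PIP4K2A knockdown, and SOX9 (-1.22) and TRIB1 (-1.09) in the double knockdown (edgeR, Benjamini-Hochberg adjusted p = 0.0151, 0.0185 and 0.0469). A further call in the PIP4K2A knockdown, RIMBP3C (-8.95), lies outside that rule and was chosen after its values were seen. For the 3 genes under the rule, over 16 libraries the values were 0.87, -2.03 and -1.01 and none passed (adjusted p = 0.627, 0.572 and 0.572). With ribosomal protein gene scaling DDIT4 stayed past the test (adjusted p = 0.00725), and SOX9 and TRIB1 stood at -1.43 and -1.29 with an adjusted p of 0.146 for both (edgeR, Benjamini-Hochberg). With the replicate number as a block DDIT4 stayed past the test at 1.44 (adjusted p = 0.0469), and SOX9 (-1.22) and TRIB1 (-1.11) did not pass at 0.0686 and 0.0911.

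Gene lists passed camera with the preset correlation (Benjamini-Hochberg), and their medians follow. In the PIP4K2A knockdown these were 0.21 for ATF4 and unfolded protein response, 0.29 for heat shock, 0.54 for histone, 0.14 for G1/S, 0.18 for G2/M, 0.16 for nucleotide excision repair, 0.22 for hnRNP, 0.15 for core spliceosome and 0.25 for extracellular matrix genes. Immediate early and AP-1 genes passed as lower there although their median was 0.002; adjusted over the list alone, 3 members were lower and 0 higher. In the PIP4K2B knockdown the medians were 0.29 for ATF4, 0.77 for histone, 0.17 for core spliceosome, 0.17 for lysosome, 0.17 for hypoxia, 0.18 for ribosomal protein, 0.22 for oxidative phosphorylation and 0.24 for extracellular matrix genes, and -0.093 for immediate early and -0.35 for mitochondrially encoded genes. In the double knockdown they were 0.25 for ATF4, 0.43 for histone, 0.13 for G1/S, 0.15 for core spliceosome, 0.17 for lysosome, 0.14 for hypoxia, 0.16 for ribosomal protein, 0.17 for oxidative phosphorylation and 0.25 for extracellular matrix genes, and -0.081 for immediate early and -0.38 for mitochondrially encoded genes. With an estimated correlation ATF4 and lysosome genes in the double knockdown passed (adjusted p = 0.0186 for each, camera, Benjamini-Hochberg) and the other 29 did not.

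These directions depend on 1 library and on the scaling. Over 16 libraries, which add the library labelled empty-vector untreated replicate 1, every positive median above turned negative, to between -0.65 and -0.15. That of mitochondrially encoded genes in the PIP4K2B knockdown turned to 0.19. With ribosomal protein gene scaling, which moved the all-gene medians to 0.03, -0.22 and -0.20 in the PIP4K2A, PIP4K2B and double knockdowns, the medians turned for core spliceosome (-0.04), lysosome (-0.04) and hypoxia genes (-0.04) in the PIP4K2B knockdown. In the double knockdown they turned for G1/S (-0.08), core spliceosome (-0.06), lysosome (-0.04), hypoxia (-0.07) and oxidative phosphorylation genes (-0.04). The ribosomal protein list also moved to -0.03 and -0.05 in these knockdowns, but that scaling centres these very genes near 0, so it says nothing of that list.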

How the results depend on the processing

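V, A, B and AB stand here for empty vector and the PIP4K2A, PIP4K2B and double knockdown, and numbers are counts of changed genes unless said otherwise, in the order V, A, B and AB. The tests of all 15-library alternatives and of single named genes were chosen after the data were seen. An alternative was taken to leave a count in place when the count stayed within 1.5 times its reported value, which says nothing of which genes were called. Causes of the changes were not tested except where given.

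RLE size factors left 17 of 17 counts of changed genes in place over 16 libraries and 17 of 17 over 15. Over 15 libraries DESeq2 left 14 of 17 in place. The replicate number as a block left 16 of 17 there, 13 of 13 counts of gene lists, and 12 of 13 lists over 16 libraries. Of 167 log2 fold changes of named genes, RLE kept 167 on their side of the test with their sign and the block 161, with the other 6 weaker. Ribosomal protein gene scaling kept 142, left 17 weaker, made 1 stronger and reversed 7. The 16-library fit kept 63, left 97 weaker and reversed 7.

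The 16-library reversals were CXCL8 (-1.39), PTGS2 (-0.83) and PIP4K2B (0.26) for UV in V, PIP4K2B (0.30) and ASNS (0.084) in untreated A, PIP4K2A (0.69) in untreated B, and CDH1 (-0.15) in untreated AB. Reversed by ribosomal protein gene scaling were PIP4K2A (-0.68) and PIP4K2C (-0.46) for UV in V, PIP4K2C for UV in B and AB (-0.55 and -0.49), KRT8 for UV in AB (-0.12), PIP4K2B in untreated A (0.074) and PIP4K2A in untreated B (0.051).

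For UV against untreated over 16 libraries, ribosomal protein gene scaling gave 15002, 1062, 2846 and 2834 genes in V, A, B and AB, where TMM gave 2642, 118, 173 and 267. No filter on low counts gave 1029, 19, 27 and 44, and DESeq2 7148, 1040, 1091 and 1247. A filter of CPM above 1 in 2 libraries gave 305, 357 and 533 in A, B and AB. With the replicate number as a block there were 161, 61, 90 and 162. With only the groups compared there were 1557, 9492 and 10408 in A, B and AB, and 0 in V (edgeR, 569 at an unadjusted p under 0.05), where the fit rests on the 2 untreated vector libraries that differ.

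For untreated A, B and AB against V the 16-library counts were 39, 157 and 45 as reported, 4579, 6983 and 6081 with ribosomal protein gene scaling, 21, 74 and 24 without a filter and 4783, 5600 and 5041 in DESeq2. The filter at CPM above 1 gave 71 and 296 in A and B, and the replicate number as a block 68 and 20 in B and AB. With only the groups compared edgeR called 0, 0 and 0 (295, 313 and 267 at an unadjusted p under 0.05). After UV the counts were 60, 127 and 64 as reported, 32, 54 and 41 without a filter, 660, 625 and 501 in DESeq2 and 507, 7151 and 6792 with only the groups compared. Ribosomal protein gene scaling gave 54 and 16 in B and AB, the stricter filter 100 and 115 in A and AB, and the replicate block 37 and 83 in A and B.

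For AB against A and B untreated, then against A and B after UV, 21, 102, 31 and 150 genes were reported over 16 libraries. Ribosomal protein gene scaling gave 6, 32, 14 and 52, no filter 6, 44, 6 and 55, DESeq2 201, 557, 520 and 712, and only the groups compared 1467, 4959, 439 and 8340. The filter at CPM above 1 gave 40 and 86 against A, and the replicate block 4 and 7 against A and 88 against B after UV. For the differences of UV responses DESeq2 called 21, 14 and 7, and edgeR called 0 in all 3 with each of the other alternatives that kept all libraries of the compared groups (217 to 6869 at an unadjusted p under 0.05).

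Over 15 libraries ribosomal protein gene scaling gave 10403, 12437, 15265 and 15282 genes for UV in V, A, B and AB, 1369 and 857 for untreated B and AB, 2151 for AB after UV, and 881 and 2302 for untreated AB against A and B. Only the groups compared gave 7350 for UV in V and 4641 and 3543 for untreated B and AB. For differences of UV responses in A, B and AB, edgeR with only the groups compared called 0, 116 and 29 (449 at an unadjusted p under 0.05 in A), and DESeq2 23, 18 and 20. In AB the count became 0 with ribosomal protein gene scaling and 0 with the replicate block (edgeR, 1153 and 1027 at an unadjusted p under 0.05).

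Leaving out each library of a comparison in turn moved 71 of 90 gene counts over 16 libraries. The lowest and highest were 3 to 22182, 2 to 6921, 2 to 7441 and 4 to 7957 for UV in V, A, B and AB, 3 to 21857, 7 to 21948 and 1 to 21962 for untreated A, B and AB, and 3 to 4598, 7 to 4288 and 1 to 3471 for A, B and AB after UV. For AB against A and B they were 1 to 1604 and 7 to 3477 untreated and 1 to 4412 and 8 to 4006 after UV. Differences of UV responses ran over 0 to 17702, 0 to 17007 and 0 to 16728, with 873 to 1747, 809 to 1655 and 731 to 1080 genes at an unadjusted p under 0.05 in edgeR where the count was 0. The highest came without untreated V replicate 2 for UV in V, untreated A, B and AB and the differences of UV responses, and without untreated V replicate 1 elsewhere. The first of these leaves the divergent library as the only untreated V library, so its counts compare that library with the rest.

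From 15 libraries, leaving out another 1 gave 2379 to 2522, 4453 to 5318 and 4956 to 5618 for UV in V, B and AB, 780 to 1895, 1099 to 1463 and 518 to 655 for untreated A, B and AB, and 2218 to 6771, 2056 to 2448 and 1465 to 1838 after UV. For AB against A and B it gave 583 to 1252 and 1782 to 2154 untreated and 1923 to 6432 and 2106 to 2266 after UV. For differences of UV responses it gave 0 to 1866 in A and 0 to 1 in AB. Counts without UV replicate 2 of A were the highest of A after UV, of AB against A after UV and of the difference of responses in A.

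Camera with the preset correlation called 15, 7, 6 and 7 of 25 lists for UV in V, A, B and AB over 16 libraries, 16, 17 and 15 in untreated A, B and AB, 3, 3 and 3 after UV and 13, 14 and 14 as differences of UV responses. With an estimated correlation it called 0 in all 13 comparisons (0 to 2 at an unadjusted p under 0.05), and fry called 0 in 11 (0 to 6) and 1 each in A and B after UV. The replicate block gave 5 in B after UV. Over 15 libraries the estimated correlation left 0, 2, 2 and 3 for UV in V, A, B and AB, 4, 4 and 2 in untreated A, B and AB, 3, 2 and 2 after UV and 0, 0 and 2 as differences of responses (5, 6 and 3 at an unadjusted p under 0.05 where the count was 0). For the differences of responses fry called 2, 2 and 2 there, and its other 10 counts stayed in place.

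With 1 library left out, list counts stayed in place in 60 of 70 cases over 16 libraries and in 50 of 50 over 15. In the comparisons that moved they ran over 9 to 19, 3 to 12, 6 to 12 and 6 to 11 for UV in V, A, B and AB, 10 to 20 and 9 to 20 in untreated B and AB, and 3 to 11, 3 to 9 and 2 to 6 in A, B and AB after UV.

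Weighted lengths had 9 calls for UV in V over 16 libraries, 1 with a mean count of at least 500, 15 with at least 30 and 2 with the replicate block. Untreated A had 1 with at least 30. Over 15 libraries the replicate block gave 39 for UV in V, 1 and 1 in untreated A and B, and 0 in A after UV (limma, 1220 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 6400 for UV in V, 0 to 6383, 0 to 6383 and 0 to 6375 in untreated A, B and AB, and 0 to 192, 0 to 2 and 0 to 2 after UV, where the highest for UV in V and for untreated cells came without untreated V replicate 2. From 15 libraries it gave 11 to 12 for UV in V, 0 in untreated A and in untreated B without replicate 1 or 2 of that knockdown (limma, 410 to 711 at an unadjusted p under 0.05), and 0 to 1720, 0 to 2 and 0 to 2 in A, B and AB after UV.

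The long-gene index of 0.20 turned to -0.36 with protein-coding genes only, -0.085 with CPM above 1, and -0.27 with protein-coding genes over 15 libraries. It kept its sign and its side of the test without any 1 library (0.016 to 0.25), with spans of 50 and 20 kb and in the blocked permutation. Correlations between backgrounds for genes of at least 5 CPM were -0.093 and -0.13 untreated for the PIP4K2B and PIP4K2A hairpins and -0.20 and -0.18 after UV. Over 15 libraries they were -0.42, -0.23, -0.20 and -0.18, and without that filter -0.20 and -0.12 untreated. Shared calls with the replicate block were 18 for A with B and 9 for B with AB untreated, and 23 for A with B and 16 for A with AB after UV. Without untreated V replicate 1 the shared calls of A with B, A with AB and B with AB were 1181, 679 and 592 untreated and 2083, 1525 and 1427 after UV.

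The spread between libraries limited what could be seen, and an effect of depth was not tested. In simulated counts a change of 2 fold between AB and V was recovered in 1.5% of genes untreated or after UV over 16 libraries, and in 77.6% untreated and 94% after UV over 15. A gene not called is therefore not shown to be unchanged, above all in the 16-library fit.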

Other observations

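Tests chosen only after the result was seen were those of genomic DNA and of a wrong label, alone or with another fault, for the divergent library, of chance values of the lone untreated vector library for the chromosomes, and all 3 for the p53 target genes. Each pattern below was found and tested on the same data and is a hypothesis.

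The library labelled empty-vector untreated replicate 1 was unlike the other 15. Shallow sequencing alone was argued against, since empty-vector untreated replicate 2 thinned to the same total kept correlations of 0.932 to 0.969 with the other 14 and had 18763 genes with a count of at least 1 after rounding where the divergent library had 30239, and a wrong label alone was argued against too, since the highest correlation with any other library was 0.512 and the lowest pair among the other 15 had 0.944. A wrong label together with another fault cannot be told apart from that fault under the given label, since the correlation with the other library of its own label was 0.469, so that the library matched no group. Reads from genomic DNA are a candidate explanation: 28813 genes with at most 5 counts over the 14 libraries of the other groups took 870.1 times the share they took in replicate 2, which had no part in choosing them (5.95% against 0.00684%), their counts rose with transcript length (rho = 0.579), and 357 of 381 olfactory receptor genes had an expected count of at least 1 against 76 to 133 elsewhere. Blood cell markers summed to 195 CPM against 6.10 to 11.6 and epithelial markers to 361 CPM against 578 to 1470, a sample from outside the series, which could raise such genes as well, stays open, and no biological explanation was tested.

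Genes of whole chromosomes moved together in the knockdowns against empty vector, downward on chromosome 21 (-0.28, -0.20, -0.11, -0.27, -0.22 and -0.18, untreated then after UV) and upward on chromosome 15, the one tested further, whose 380 of 11120 genes had medians of 0.16, 0.15, 0.29, 0.17, 0.18 and 0.33 in the 6 comparisons after a trend on GC content was removed, against at most 0.062 to 0.087 in 10000 random lists. GC content was argued against, since the lowest of these medians was 0.154. Chance values of the lone untreated vector library were argued against, since the medians of 22 chromosomes correlated at 0.973 or more between the untreated and the UV comparisons, which use other libraries. Copy number that differs between the empty-vector line and the knockdown lines is a candidate explanation. The shift was above 0 in 36 of 36 parts of chromosome 15 split by level or position, the lowest at 0.075. Since the chromosome's median was already high, the sign of its parts is weak support. The shift was also uneven, largest at the start of the chromosome in all 6 comparisons. By position it was 0.363, 0.137 and 0.075 in the untreated PIP4K2B knockdown, so an even gain of the whole chromosome was not shown. An effect of the knockdown itself stays open and was not tested.

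The p53 target genes were higher in all 3 knockdowns than in empty vector, untreated and after UV. Chance values of the lone untreated vector library were argued against by the UV comparisons, where the lowest median was 0.286. With ribosomal protein gene scaling the lowest median over 6 comparisons was 0.377. That scaling raised the median of all genes in the untreated PIP4K2A knockdown, so it could not have lowered the list there. It therefore does not by itself decide whether the scaling of the libraries plays a part. Taking off the median of each gene's chromosome left 0.34, 0.43 and 0.24 untreated and 0.23, 0.37 and 0.31 after UV. A scaling factor moves all genes of a library alike and cancels in these values. They therefore argue against scaling alone for the rise after UV. Shifts common to a whole chromosome did not account for the whole rise. Shifts of parts of a chromosome, which a single median cannot remove, stay open. Expression of a hairpin as such cannot be told apart from the loss of the kinases, because no hairpin without a target was used here: cells with both hairpins against those with 1 had medians of -0.12 and -0.28 untreated and 0.007 and -0.05 after UV. A shared effect of lowering either kinase likewise stays open, as untested.

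Replicates of the PIP4K2A knockdown after UV differed more than those of the other groups apart from untreated empty vector, with a chi-square per degree of freedom of 94.4 against 1.80 to 21.1, a correlation of 0.979, and 27716 and 29403 genes with an expected count of at least 1.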
